A study of Mus musculus with 12 samples.

How the data were processed

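Total RNA from the livers of 12 male C57BL/6 mice was measured, 1 mouse per array, on whole-transcript mouse arrays, with biotin labelling per the labels. The mice were WT or KO for Ahnak and were fed chow or HFD (60% fat) for 8 weeks in weight-matched groups, 3 mice per group. The deposited table holds log2 signals for 41345 probe sets on 12 arrays, made with oligo per the submitters' processing notes. The version of oligo and the exact method are not given in the sources used here. The values run from 1.40 to 14.36 with 0 missing, and they were used as deposited, with no further scaling.

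Gene symbols came from the array annotation, joined to a table of RefSeq gene names for assembly GRCm38.p6, which was used only for symbols and for the order of the neighbours of Ahnak. Of the probe sets, 23521 carried exactly 1 symbol, 23328 of them matched by gene number and 193 not, 1814 carried several symbols, and 16010 had no name here. Genes with over 1 probe set (1082 of 22180) were represented by the probe set with the highest mean over all arrays. No filter on dim genes was used. The 17824 probe sets without a single symbol were left out of the counts of genes.

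The 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 1 value per gene. There were 6 comparisons: KO against WT on chow and on HFD, the mean of these, HFD against chow in WT and in KO, and the interaction. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) of the fit, and levels with the standard deviation (SD) of 3 mice. Arrays of 2 groups were said not to overlap where every array of one group lay above every array of the other.

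Of 35 gene lists 34 were tested, the list of erythroid genes having 4 measured members where 5 were needed. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Whether a list shifted is stated by camera at the preset correlation unless another test is named. Their p values were adjusted over all lists within a comparison. Counts of members are given with the adjustment over all genes and with the adjustment over the list alone. The comparisons, the tests of genes and lists, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The clock index and the tests of adipose tissue, female animals, cross-hybridisation and growth hormone signalling were chosen after the results were seen.

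The rule for named genes took, for each comparison, the 10 largest rises and the 10 largest falls among genes with 1 symbol that passed the threshold and, for comparisons of 2 groups, did not overlap between arrays. Gene models, clones and unnamed transcripts were left out. Where fewer passed, the genes with the smallest p values were added as not passing. Up to 4 members of each list with the smallest p values, and any member as an example, could be named. Always included were Ahnak, Nnt, Ppara, Fgf21, Cpt1a, Pparg, Cidec, Cd36, Srebf1, Scd1, Fasn, Cyp7a1, Pck1, G6pc, Tnf and Ccl2.

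Comparisons that share the WT HFD arrays were compared with 100 simulations of unchanged groups that share the same arrays. The counts of changed genes were compared with those from other splits of the same arrays, 10 splits for 2 groups and 100 for the average and the interaction. The alternatives tried were a replicate block, eBayes with trend and robust settings, array weights, quantile normalization, centring on the median, only genes above the median signal, the mean of all probe sets of a gene, every probe set, only the arrays compared, a change of at least 2-fold, and leaving out each of the 12 arrays in turn.

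The code was tested on simulated data with the layout of KO against WT on HFD and 22180 genes. It recovered 37.3% of genes (25 of 67) with a true log2 fold change of 0.5, 86.6% (58 of 67) at 1 and 100% (66 of 66) at 2, and it called 3 of 21960 unchanged genes. Of 100 simulated lists without a shift 2 passed before adjustment. The simulated genes varied independently of each other, so this share does not carry over to lists of correlated genes. Estimated correlations in the real lists reached 0.69, for cholesterol synthesis.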

Results

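Gene expression was measured in the livers of 12 male C57BL/6 mice, 1 mouse per array. Wild-type (WT) mice and mice lacking Ahnak (KO), which encodes a very large scaffold protein at the cell membrane, were fed regular chow or a high-fat diet (HFD, 60% fat) for 8 weeks. Each of the 4 groups held 3 mice. Every array gave a log2 signal for 41345 probe sets, from 1.40 to 14.36, with array medians between 5.58 and 5.70. Of these probe sets, 23521 carried a single gene symbol and represented 22180 genes. Across genes, which are not independent replicates, arrays of the same group correlated with r between 0.992 and 0.994. The number of arrays limits the precision of every value.

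The 3 livers of WT mice on HFD stood apart from the other 9. They scored 30.0 to 32.3 on the first principal component, which held 32.2% of the variance, while the other arrays scored -18.5 to -3.95. Group means lay closest for WT and KO on chow, with a root mean square difference of 0.17 on the log2 scale over all genes, and farthest for WT and KO on HFD, with 0.33. WT mice on chow and on HFD differed by 0.29, and KO mice on chow and on HFD by 0.20.

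**Figure D1:**
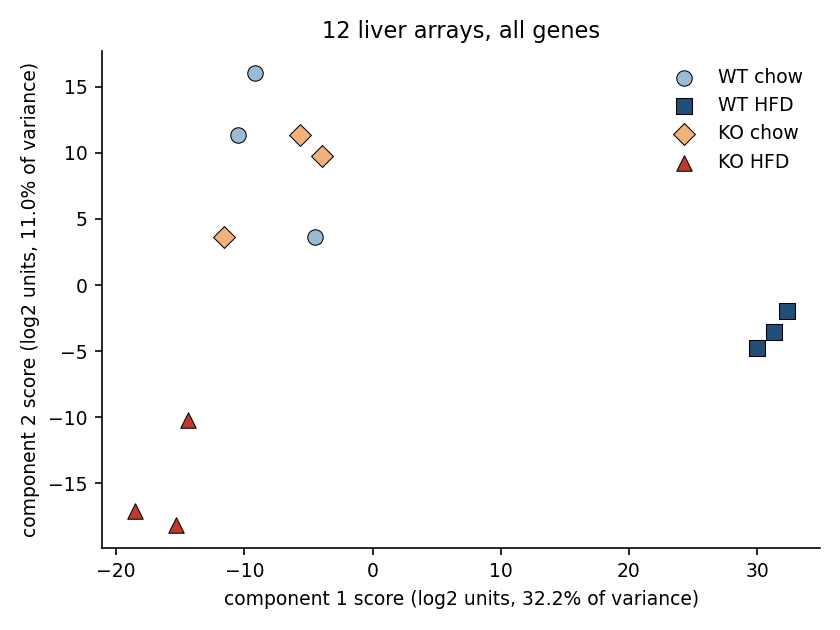
Scores of the 12 arrays on the first principal components of all genes (log2 units, with the share of variance on each axis); each point is 1 mouse and each group has its own colour and marker. The 3 WT HFD arrays lie at 30.0 to 32.3 on component 1 and the other 9 at -18.5 to -3.95.

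Ahnak, the gene the KO mice lack, was covered by 1 probe set. Its log2 signals were 6.50, 6.83 and 6.58 in WT on chow, 7.26, 7.06 and 6.74 in WT on HFD, 6.38, 6.74 and 6.66 in KO on chow, and 6.46, 6.52 and 6.62 in KO on HFD. The KO minus WT log2 fold change was -0.04 ± 0.14 (SE) on chow, with a limma adjusted p = 0.971, and -0.48 ± 0.14 on HFD, with an adjusted p = 0.0483. The call on HFD held when WT chow 2, WT HFD 3 or KO chow 1 was left out and was lost without any of the other 9 arrays, with an adjusted p of up to 0.173 without WT HFD 1. Which part of the gene was deleted is not given in the sources used here, and a probe set outside that part checks nothing, so the Ahnak signal was not taken as a check of the labels.

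The first question of the design is how the livers of KO and WT mice differ on regular chow. Only 2 of 22180 genes changed, both higher in KO, and both are known as genes with higher expression in female than in male mouse liver. With trend and robust settings 5 genes were higher and 13 lower, and among genes above the median signal 4 and 11, so the count and its balance depend on the settings. Fmo2, a flavin-containing monooxygenase, rose by 1.23 ± 0.15 (log2 fold change ± SE, adjusted p = 0.0307), from 8.97 ± 0.06 (SD, n = 3) in WT to 10.21 ± 0.40 in KO. Cux2, a homeobox transcription factor, rose by 0.79 ± 0.09 (adjusted p = 0.0254), from 6.74 ± 0.05 to 7.53 ± 0.12. Among the 18 measured female-biased liver genes these 2 rose, 0 fell and 16 did not pass, while 5 rose when adjusted over the list alone. As a group the female-biased genes were higher in KO (camera adjusted p = 2.26e-05), although the adjusted p = 0.387 with an estimated correlation. The 19 male-biased genes were lower as a group (adjusted p = 4.13e-10, and adjusted p = 0.387 with an estimated correlation). None of the male-biased genes passed over all genes, but 10 were lower when adjusted over the list alone, including Cspg5 (-1.10 ± 0.19), the glucuronosyltransferase gene Ugt2b38 (-1.28 ± 0.28) and the cytochrome P450 gene Cyp2u1 (-0.72 ± 0.15). In KO on chow Ugt2b38 averaged 4.68, near the signal of Xist, which male cells do not express (4.21 to 4.76 here). The size of the fall of Ugt2b38 is therefore less certain than its direction.

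A further 8 lists shifted between KO and WT on chow without a single member passing over all genes. Drug and steroid metabolism genes (adjusted p = 0.0456), acute phase genes (0.00618) and stellate cell and fibrosis genes (0.00402) were higher in KO. Lower in KO were fatty acid oxidation genes (0.0176), NRF2 targets (0.00945), genes of the unfolded protein response (0.00618), TGF beta targets (0.0182) and cell cycle genes (0.0182). Their adjusted p values were 0.819 to 0.864 with an estimated correlation. Adjusted over the list alone, 2 fatty acid oxidation genes and 2 NRF2 targets were lower, 1 drug metabolism gene was higher, and no member of the other 5 lists passed. Acaa1b, a peroxisomal thiolase, stood at -0.54 ± 0.09 (adjusted p = 0.0903) and Gclc, the catalytic subunit of glutathione synthesis, at -0.59 ± 0.11 (0.184).

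None of the lipid genes named in advance passed between KO and WT on chow. Cd36, a fatty acid transporter, differed by 0.10 ± 0.21, Scd1, the stearoyl-CoA desaturase, by -0.20 ± 0.34, the hormone gene Fgf21 by -0.01 ± 0.30, and Fasn, the fatty acid synthase, by -0.08 ± 0.14. Pparg, a nuclear receptor of lipid storage, stood at -1.26 ± 0.49 (adjusted p = 0.63) and Srebf1, which drives lipid synthesis, at -0.31 ± 0.13 (0.655). The remaining genes named in advance were also below the threshold, among them Cidec (0.41 ± 0.40), Nnt (-0.23 ± 0.30), Ccl2 (-0.27 ± 0.21), Cpt1a (0.14 ± 0.08), Cyp7a1 (-0.12 ± 0.24), Tnf (-0.08 ± 0.10), G6pc (-0.09 ± 0.10) and Pck1 (-0.03 ± 0.07). Cyp2c69 (1.34 ± 0.19, adjusted p = 0.0855), Spon2 (-0.89 ± 0.13, adjusted p = 0.0855) and Nt5dc2 (-0.57 ± 0.08, adjusted p = 0.054) did not pass either. An unadjusted p under 0.05 was found for 1558 genes, and the arrays of the 2 groups did not overlap for 13.2% of all genes, where chance gives 10%.

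The calls on chow were lost without single arrays, among them HFD arrays, which enter this comparison only through the spread estimated over all groups. Leaving out 1 array gave 0 to 5 changed genes, with 0 without WT chow 3, WT HFD 1, WT HFD 2, KO chow 2, KO chow 3, KO HFD 1 or KO HFD 2, 1 without WT HFD 3, 4 without KO HFD 3 and 5 without WT chow 1. Fmo2 passed only without KO chow 1 or KO HFD 3, and Cux2 only without WT chow 1, WT HFD 3, KO chow 1 or KO HFD 3; without WT chow 3 their adjusted p values were 0.207 and 0.148. The sex-biased lists kept their calls whichever array was left out, and the other 8 lists each lost theirs without at least 1 array. Their highest adjusted p values were 0.152 for fibrosis and 0.159 for the unfolded protein response without WT chow 3, 0.127 for acute phase and 0.268 for fatty acid oxidation without WT chow 2, and 0.333 for cell cycle and 0.271 for TGF beta targets without WT chow 1. NRF2 targets reached 0.098 without KO chow 2 and drug metabolism genes 0.25 without KO chow 3.

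On HFD, the livers of KO and WT mice differed widely, in 2331 of 22180 genes, of which 862 were higher and 1469 lower in KO. With each array centred on its median the split was 545 and 1937. The largest measured fall was that of Cyp2b9, a cytochrome P450 gene of female mouse liver, by 8.44 ± 0.94 on the log2 scale (adjusted p = 0.000196), from 13.29 ± 0.12 (SD, n = 3) in WT to 4.85 ± 1.17 in KO. The largest measured rise was that of Moxd1, a monooxygenase gene of male mouse liver, by 4.80 ± 0.29 (adjusted p = 1.93e-06), from 4.75 ± 0.12 to 9.55 ± 0.76. Their lower levels lie near those of Xist, which male cells do not express and which read 4.21 to 4.76 here, so their sizes are less certain than their directions. The same holds for Cyp2b10, Cyp2b13, Cyp3a44, Slc22a27 and Ugt2b38 in this comparison. Lists of lipid synthesis, cytokine, fibrosis and cell cycle genes were lower in KO by camera, and fatty acid oxidation genes were higher. With an estimated correlation 0 of 34 lists passed, and the adjusted p values of these 5 were 0.196, 0.0544, 0.117, 0.0544 and 0.219. The WT livers of this comparison are the 3 that stood apart on the first component (30.0 to 32.3). They also stood apart in a clock gene index chosen after the results were seen, with 0.54 or more against 0.03 or less on the other 9 arrays.

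Male-biased and female-biased liver genes differed in opposite directions between KO and WT on HFD. Of 19 male-biased genes 14 rose, 1 fell and 4 did not pass, and adjusted over the list alone 15 rose and 1 fell (camera adjusted p = 1.27e-15, and adjusted p = 0.0544 with an estimated correlation). Besides Moxd1, Cyp4a12b, a fatty acid hydroxylase gene, rose by 3.11 ± 0.18, Cyp7b1, an oxysterol hydroxylase gene, by 2.66 ± 0.24, Ugt2b38 by 2.70 ± 0.28, the steroid dehydrogenase gene Hsd3b5 by 2.44 ± 0.51 and Selenbp2 by 2.37 ± 0.28. The member that fell was Cyp2u1 (-0.88 ± 0.15). Of 18 female-biased genes 0 rose, 7 fell and 11 did not pass, with 7 also lower when adjusted over the list alone (adjusted p = 0.000423, and adjusted p = 0.177 with an estimated correlation). Cyp2b13 fell by 4.89 ± 0.31, Cyp2a4 by 3.22 ± 0.15 and Cyp3a44 by 1.46 ± 0.18.

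Drug and steroid metabolism genes, targets of the receptors CAR, PXR and AhR, were lower in KO on HFD: 0 of 21 rose, 10 fell and 11 did not pass, and adjusted over the list alone 1 rose and 11 fell (adjusted p = 1.91e-08, and adjusted p = 0.115 with an estimated correlation). Cyp2b10, a classic CAR target, fell by 3.43 ± 0.47, Cyp2a5 by 3.17 ± 0.11 and the PXR target Cyp3a11 by 0.93 ± 0.15. Cyp2b9, Cyp2b13 and Cyp2a4 belong to this list as well as to the female-biased one. Of 19 NRF2 targets and glutathione genes 0 rose, 8 fell and 11 did not pass, and adjusted over the list alone 3 rose and 9 fell (adjusted p = 9.48e-05, and adjusted p = 0.115 with an estimated correlation). The glutathione transferase genes Gstm3 and Gsta3 fell by 3.11 ± 0.35 and 1.38 ± 0.13, and the quinone reductase gene Nqo1 by 1.02 ± 0.14.

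Lipid synthesis genes were lower in KO on HFD and fatty acid oxidation genes higher. Of 24 genes of fatty acid and triglyceride synthesis 4 rose, 10 fell and 10 did not pass, with 4 and 11 adjusted over the list alone (adjusted p = 0.00446, and adjusted p = 0.196 with an estimated correlation). Thrsp, a regulator of lipogenesis, fell by 3.72 ± 0.20, Scd1 by 2.05 ± 0.34, the acyltransferase gene Mogat1 by 1.58 ± 0.20, Srebf1 by 0.91 ± 0.13 and Fasn by 0.64 ± 0.14. Elovl5, a fatty acid elongase gene, rose by 0.56 ± 0.09. Of 30 genes of fatty acid oxidation, targets of PPAR alpha, 12 rose, 0 fell and 18 did not pass, and adjusted over the list alone 17 rose and 2 fell (adjusted p = 4.79e-07, and adjusted p = 0.219 with an estimated correlation). Fgf21 rose by 1.95 ± 0.30, Cyp4a31 by 1.81 ± 0.13, the peroxisomal enzyme gene Ehhadh by 1.11 ± 0.09 and Cpt1a, the entry step of mitochondrial oxidation, by 0.51 ± 0.08. Ppara itself stood at -0.14 ± 0.09 (adjusted p = 0.386). The call of Fasn was lost without KO HFD 2 (adjusted p = 0.057) or KO HFD 3 (0.0518).

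Lipid droplet genes went both ways: of 21 measured, 5 rose, 8 fell and 8 did not pass, with 6 and 9 adjusted over the list alone. Cidea, a droplet fusion protein gene, fell by 2.76 ± 0.40, Cd36 by 2.24 ± 0.21 and Plin4 by 1.82 ± 0.19, while the lipase gene Pnpla2 rose by 0.75 ± 0.14 and Plin2 by 0.45 ± 0.07. The list did not shift by camera (adjusted p = 0.392) but passed with fry (adjusted p = 0.0122), with a mean of -0.44 and a median of 0.0042. Pparg fell by 1.77 ± 0.49 (adjusted p = 0.037), a call lost without any 1 of the 6 HFD arrays, with an adjusted p of 0.0768, 0.087 and 0.111 without WT HFD 1, 2 and 3 and of 0.128, 0.0556 and 0.0593 without KO HFD 1, 2 and 3. Cidec (1.16 ± 0.40, adjusted p = 0.092) and Nnt (-0.79 ± 0.30, adjusted p = 0.12) did not pass.

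Bile acid genes changed in both directions, 4 up and 6 down of 21, with 5 and 6 adjusted over the list alone and no shift of the list (adjusted p = 0.703; mean 0.0032, median -0.11). Cyp8b1, which sets the share of cholic acid, rose by 0.96 ± 0.11 and Akr1d1, a bile acid reductase gene, fell by 1.87 ± 0.24, while Cyp7a1, the rate-limiting enzyme, stood at 0.79 ± 0.24 (adjusted p = 0.0583). Of 21 genes of glucose metabolism and insulin signalling 6 rose and 7 fell, with 8 and 8 adjusted over the list alone (adjusted p = 0.724). Irs2, an insulin receptor substrate gene, rose by 1.99 ± 0.30 and the glycolytic gene Pklr fell by 1.09 ± 0.14. G6pc, the last step of glucose output, rose by 0.37 ± 0.10, a call lost without WT HFD 1, WT HFD 2, WT HFD 3, KO chow 2, KO HFD 1 or KO HFD 2 (adjusted p of up to 0.112). Pck1 stood at 0.25 ± 0.07 (adjusted p = 0.0532). Of 16 secreted liver hormones 7 rose and 2 fell, with 7 and 2 also when adjusted over the list alone (adjusted p = 0.00181, and adjusted p = 0.0544 with an estimated correlation). Igfbp1 and Igfbp2, which bind insulin-like growth factors, rose by 2.22 ± 0.30 and 2.02 ± 0.12, and Serpina6, which carries corticosteroids, fell by 1.55 ± 0.20.

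Markers of recruited macrophages and inflammatory genes were lower in KO on HFD. Of 16 lipid-associated and recruited macrophage markers 0 rose, 11 fell and 5 did not pass, and adjusted over the list alone 1 rose and 14 fell (adjusted p = 3.85e-09, and adjusted p = 0.0544 with an estimated correlation). Mmp12, an elastase gene of macrophages, fell by 1.73 ± 0.13, Gpnmb by 1.41 ± 0.21 and Trem2 by 0.79 ± 0.16. Of 20 Kupffer cell and macrophage markers 3 fell, with 5 adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.582 with an estimated correlation). Mpeg1 fell by 0.96 ± 0.13. The list's call was lost without WT HFD 3 or KO HFD 2, where its adjusted p reached 0.097. Of 24 cytokine and chemokine genes 1 rose, 9 fell and 14 did not pass, with 1 and 11 adjusted over the list alone (adjusted p = 1.19e-05, and adjusted p = 0.0544 with an estimated correlation). Cxcl10 fell by 1.80 ± 0.21 and Ccl2, which draws in monocytes, by 1.28 ± 0.21, whereas Il1b rose by 1.90 ± 0.33. Tnf fell by 0.36 ± 0.10 (adjusted p = 0.0466), a call that held only without WT HFD 3 or KO HFD 2 and reached an adjusted p of 0.169 without WT HFD 2. Of 24 interferon response genes 0 rose, 11 fell and 13 did not pass, with 17 lower when adjusted over the list alone (adjusted p = 9.33e-10, and adjusted p = 0.115 with an estimated correlation), such as Ifit1 (-1.53 ± 0.23) and Gbp3 (-1.13 ± 0.19).

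Genes of stellate cells and fibrosis, cell division and protein folding were lower as groups in KO on HFD. Of 28 stellate cell and fibrosis genes 0 rose, 10 fell and 18 did not pass, with 11 lower when adjusted over the list alone (adjusted p = 6.64e-09, and adjusted p = 0.117 with an estimated correlation). The collagen genes Col3a1 and Col1a1 fell by 1.24 ± 0.14 and 1.10 ± 0.13, and Timp1, an inhibitor of matrix proteases, by 1.29 ± 0.17. Of 27 cell cycle genes 0 rose, 17 fell and 10 did not pass, with 18 lower when adjusted over the list alone (adjusted p = 1.02e-10, and adjusted p = 0.0544 with an estimated correlation), among them Ccnb2 (-1.36 ± 0.15), Cdk1 (-0.94 ± 0.15) and the proliferation marker Mki67 (-0.84 ± 0.11). Of 23 genes of the unfolded protein and integrated stress response 2 rose, 13 fell and 8 did not pass, with 3 and 14 adjusted over the list alone (adjusted p = 2.38e-06, and adjusted p = 0.115 with an estimated correlation). The chaperone gene Hspa5 fell by 1.20 ± 0.17 and Creld2 by 1.89 ± 0.16. The members that rose were Atf5, by 1.31 ± 0.13, and Fgf21, by 1.95 ± 0.30. Acute phase genes did not shift as a list (adjusted p = 0.11), although of 25 members 2 rose and 5 fell, with 2 and 6 adjusted over the list alone, among them Orm3 (-3.48 ± 0.37).

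Other genes with large differences on HFD were Fabp5, a fatty acid-binding protein gene, up by 2.71 ± 0.27, Ugt2b37, up by 2.80 ± 0.26, Cgref1, up by 2.45 ± 0.45, and Lepr, the leptin receptor gene, up by 2.63 ± 0.66. Hamp2, a hepcidin gene, fell by 4.59 ± 0.33, Slc22a27, an organic anion transporter gene near Ahnak on chromosome 19, by 4.02 ± 0.28, Rgs16 by 3.60 ± 0.65, Lgals1, which encodes galectin, by 3.38 ± 0.17, and Serpina7, which carries thyroxine, by 3.42 ± 0.62. Of the 20 largest changes only that of Lepr was lost when 1 array was left out, namely without KO HFD 2 (adjusted p = 0.102), WT HFD 3 (0.0744), WT HFD 1 (0.0691) or WT HFD 2 (0.0637). A change of at least 2-fold was reached by 295 of the 2331 genes, and 5283 genes had an unadjusted p under 0.05. The arrays did not overlap for 2327 of the changed genes and for 28.6% of all genes, where chance gives 10%. The count fell to 1506 without WT HFD 3.

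**Figure D2:**
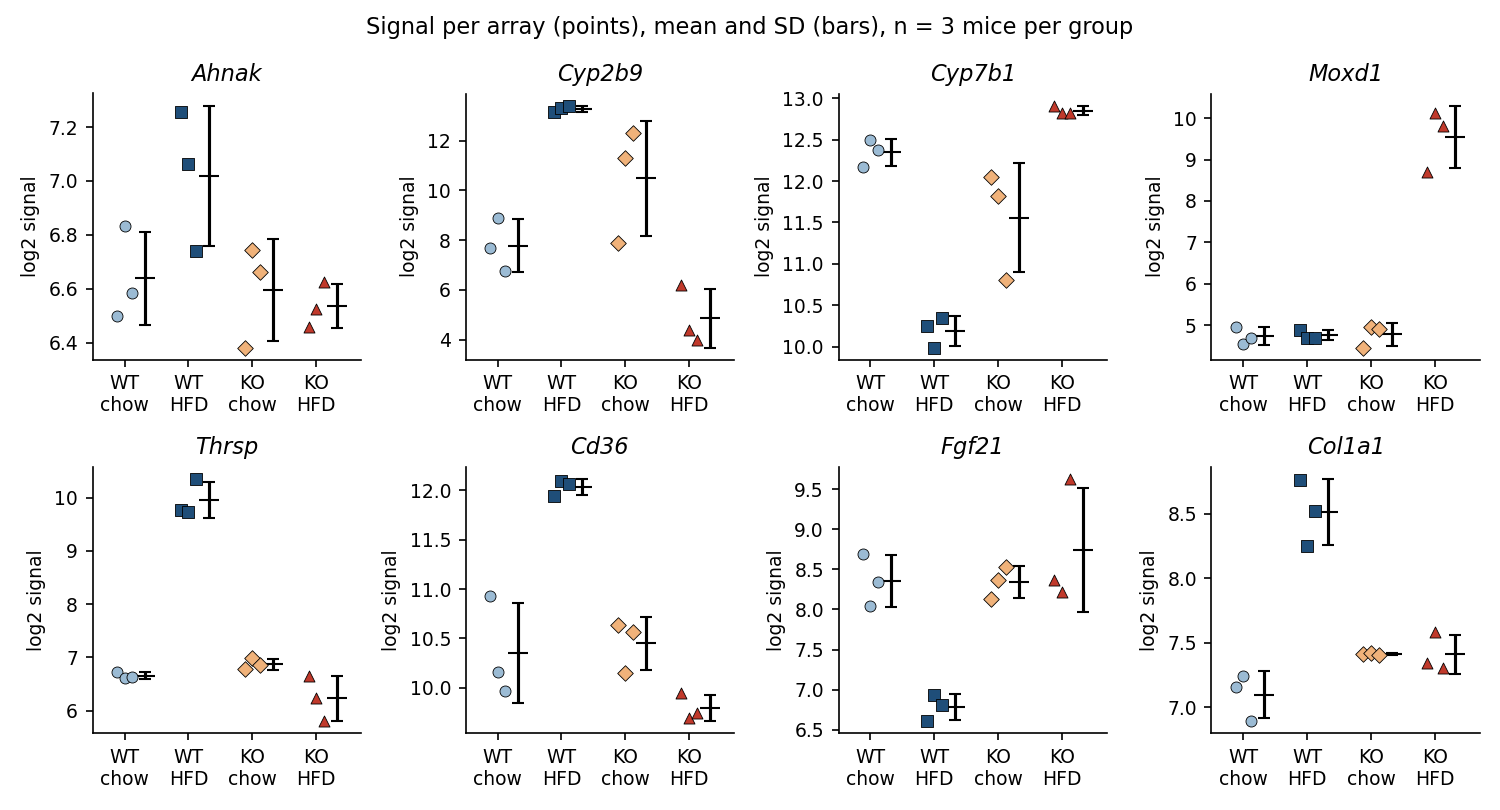
Log2 signal of 8 genes in each liver; points are single mice, and bars give the mean and SD of the 3 mice per group, with a separate vertical axis for each gene. Cyp2b9 lies at 13.29 ± 0.12 in WT on HFD and at 4.85 ± 1.17 in KO on HFD, and Moxd1 is near 4.75 in all groups but KO on HFD (9.55 ± 0.76).

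In WT mice, HFD changed 1543 of 22180 genes against chow, 891 up and 652 down, and 1089 and 457 with each array centred on its median. Lists of fibrosis, recruited macrophage, interferon response and cell cycle genes were higher by camera, and fatty acid oxidation and male-biased genes were lower. With an estimated correlation recruited macrophage and cell cycle genes passed (adjusted p = 0.048), while fibrosis and male-biased genes (0.0559) and interferon response and fatty acid oxidation genes (0.178) did not. Cyp2b9 rose most, by 5.52 ± 0.94 (adjusted p = 0.0044), from 7.77 ± 1.07 (SD, n = 3) to 13.29 ± 0.12. Cyp4a12b fell most, by 3.36 ± 0.18 (adjusted p = 2.48e-06), from 12.07 ± 0.07 to 8.71 ± 0.21. Levels near that of Xist also enter the changes of Cidea, Cyp2b13, Orm3, Slc22a27 and Ugt2b38 in WT mice. This comparison is implied by the layout of the study and gives the background against which the KO mice are read.

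Stellate cell and fibrosis genes rose in WT on HFD (camera adjusted p = 2.21e-14, and adjusted p = 0.0559 with an estimated correlation). Of 28 measured, 12 rose, 0 fell and 16 did not pass, with 21 higher when adjusted over the list alone. Col1a1 rose by 1.42 ± 0.13, Col3a1 by 1.32 ± 0.14 and Timp1 by 1.41 ± 0.17. Of 16 recruited macrophage markers 10 rose, 1 fell and 5 did not pass, with 13 and 1 adjusted over the list alone (adjusted p = 3.07e-10, and adjusted p = 0.048 with an estimated correlation). Mmp12 rose by 2.02 ± 0.13, Gpnmb by 1.90 ± 0.21 and Trem2 by 1.01 ± 0.16, while Cd9 fell by 0.47 ± 0.10. Kupffer cell markers were higher (adjusted p = 0.000227, and adjusted p = 0.451 with an estimated correlation) with 2 of 20 passing, 3 adjusted over the list alone, such as Mpeg1 (0.99 ± 0.13). Of 24 interferon response genes 7 rose, with 11 adjusted over the list alone (adjusted p = 2.36e-07, and adjusted p = 0.178 with an estimated correlation), such as Gbp3 (1.08 ± 0.19). Cytokine genes were higher (adjusted p = 0.00254, and adjusted p = 0.171 with an estimated correlation), with 6 up and 2 down of 24, 13 and 3 adjusted over the list alone. Ccl2 rose by 1.18 ± 0.21 and Il1b fell by 2.38 ± 0.33, while Tnf stood at 0.27 ± 0.10 (adjusted p = 0.161).

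Acute phase genes were higher in WT on HFD (adjusted p = 0.000346, and adjusted p = 0.451 with an estimated correlation): of 25 measured, 7 rose, 1 fell and 17 did not pass, with 8 and 1 adjusted over the list alone. Orm3 rose by 4.08 ± 0.37, Lcn2, which binds bacterial siderophores, by 2.89 ± 0.43 and Saa3 by 1.51 ± 0.31. Of 27 cell cycle genes 7 rose, with 16 adjusted over the list alone (adjusted p = 3.95e-09, and adjusted p = 0.048 with an estimated correlation), such as Ccnb2 (1.11 ± 0.15) and Mki67 (0.61 ± 0.11). Of 23 genes of the unfolded protein and integrated stress response 12 rose and 3 fell, with 14 and 4 adjusted over the list alone (adjusted p = 8.36e-05, and adjusted p = 0.184 with an estimated correlation). Ddit3, a stress-induced transcription factor gene, rose by 1.24 ± 0.22 and Hspa5 by 0.78 ± 0.17. The members that fell were Asns (-2.31 ± 0.60), Fgf21 (-1.57 ± 0.30) and Atf5, the last by 0.98 ± 0.13.

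Fatty acid oxidation genes fell in WT on HFD, 11 of 30 with 0 up and 19 not passing, and 15 when adjusted over the list alone (adjusted p = 2.12e-09, and adjusted p = 0.178 with an estimated correlation). Acot1 fell by 1.90 ± 0.18, Pdk4, which holds back glucose oxidation, by 1.77 ± 0.23, Cyp4a31 by 1.74 ± 0.13 and Fgf21 by 1.57 ± 0.30. Cpt1a fell by 0.31 ± 0.08 (adjusted p = 0.0345), a call lost without WT chow 1 (adjusted p = 0.108), WT chow 2, KO chow 2 or any WT HFD array. Lipid synthesis genes did not shift as a list (adjusted p = 0.357), although 6 of 24 rose and 2 fell, with 6 and 3 adjusted over the list alone. Thrsp rose by 3.30 ± 0.20, Mogat1 by 1.64 ± 0.20 and Srebf1 by 0.56 ± 0.13, the last call being lost without WT chow 1 (adjusted p = 0.0658) or WT HFD 3 (0.081), and Fasn (0.23 ± 0.14) and Scd1 (0.11 ± 0.34) did not pass. Of 21 lipid droplet genes 6 rose and 4 fell, with 8 and 5 adjusted over the list alone and no shift of the list (adjusted p = 0.155). Cidea rose by 2.82 ± 0.40 and Cd36 by 1.68 ± 0.21, while Pparg stood at 0.92 ± 0.49 (adjusted p = 0.322) and Cidec at 0.08 ± 0.40. Cholesterol synthesis genes were lower (adjusted p = 0.00254, and adjusted p = 0.602 with an estimated correlation), 2 of 19 by themselves and 2 adjusted over the list alone, such as Hsd17b7 (-1.12 ± 0.09); without WT chow 3 the list's adjusted p was 0.132.

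Male-biased liver genes fell in WT on HFD: of 19, 1 rose, 11 fell and 7 did not pass, with 1 and 13 adjusted over the list alone (adjusted p = 7.89e-13, and adjusted p = 0.0559 with an estimated correlation). Ugt2b38 fell by 2.34 ± 0.28, Cyp7b1 by 2.16 ± 0.24 and Hsd3b5 by 2.13 ± 0.51, while Cyp2u1 rose by 0.85 ± 0.15. Female-biased genes did not shift as a list (adjusted p = 0.108), with 4 up and 1 down of 18, 7 and 3 adjusted over the list alone, such as Cyp2b13 (4.60 ± 0.31) and Cyp3a44 (-1.45 ± 0.18). Drug metabolism genes were higher (adjusted p = 0.0257, and adjusted p = 0.473 with an estimated correlation), with 5 up and 2 down of 21, 6 and 2 adjusted over the list alone; Cyp2b10 rose by 2.58 ± 0.47, and Cyp3a11 fell by 1.10 ± 0.15. That list's adjusted p was 0.103 without WT chow 1. Secreted liver hormones were lower (adjusted p = 0.000281, and adjusted p = 0.048 with an estimated correlation), with 1 up and 5 down of 16, 1 and 7 adjusted over the list alone. Igfbp1 and Igfbp2 fell by 2.23 ± 0.30 and 2.05 ± 0.12. In the list of glucose metabolism Irs2 fell by 2.29 ± 0.30 and G6pc by 0.47 ± 0.10, where 5 of 21 members rose and 6 fell (7 and 8 adjusted over the list alone; adjusted p = 0.538). The G6pc call was lost without 4 of the 12 arrays, with an adjusted p of up to 0.0727 without WT chow 3. Below the threshold were Pck1 (-0.27 ± 0.07, adjusted p = 0.051), Cyp7a1 (-0.27 ± 0.24), Ppara (0.18 ± 0.09), Nnt (0.31 ± 0.30) and Ahnak (0.38 ± 0.14, adjusted p = 0.141).

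Other large changes with HFD in WT mice were the rises of Rgs16 (3.79 ± 0.65), Slc22a27 (3.51 ± 0.28), Sprr1a (2.80 ± 0.12) and Ciart (2.77 ± 0.32), a repressor of the circadian clock. Falls were found for the kinase gene Sik1 (-2.32 ± 0.43), for Asns (-2.31 ± 0.60), which makes asparagine, for Csad (-2.28 ± 0.16), an enzyme of taurine synthesis, and for Adgrf1 (-2.19 ± 0.51). Clock output genes minus clock genes of the opposite phase, an index chosen after the results were seen, averaged 0.54 or more on each WT HFD array. On each of the other 9 it was 0.03 or less. Asns kept its call without only 2 of the 12 arrays, and its adjusted p reached 0.111 without WT chow 3; Adgrf1 lost its call without WT chow 1, WT chow 3 or any WT HFD array (adjusted p of up to 0.0776). A change of at least 2-fold was reached by 206 of the 1543 genes, and 4569 genes had an unadjusted p under 0.05. The arrays did not overlap for 1537 of the changed genes and for 26.4% of all genes, where chance gives 10%. The count was 815 without WT chow 3, and 935, 860 and 867 without WT HFD 1, WT HFD 2 and WT HFD 3.

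In KO mice, HFD changed 54 of 22180 genes against chow, 19 up and 35 down, and 20 and 47 with each array centred on its median. The count was 124 with trend and robust settings, 111 among genes above the median signal and 21 with only the arrays compared. Moxd1 rose most, by 4.77 ± 0.29 (adjusted p = 8.18e-06), from 4.77 ± 0.28 (SD, n = 3) to 9.55 ± 0.76, followed by Saa3, an acute phase gene, by 3.09 ± 0.31 (adjusted p = 0.00104). Cyp2b9 fell most, by 5.64 ± 0.94 (adjusted p = 0.0316), from 10.49 ± 2.32 to 4.85 ± 1.17. The fall of Cyp2b9 was a call lost without WT HFD 1, 2 or 3, KO chow 2 or 3, or KO HFD 2 or 3, with an adjusted p of up to 0.141 without KO chow 2. Levels near that of Xist enter the changes of Moxd1, Cyp2b9, Cyp3a44, Rnase2a and Ugt2b38 in KO mice, so their sizes are less certain than their directions.

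Drug and steroid metabolism genes fell as a group in KO on HFD (camera adjusted p = 3.11e-18, and adjusted p = 0.0381 with an estimated correlation): of 21, 0 rose, 5 fell and 16 did not pass, with 9 lower when adjusted over the list alone. Cyp2a4, Cyp2a5 and Cyp3a11 fell by 2.56 ± 0.15, 2.46 ± 0.11 and 2.05 ± 0.15. Female-biased liver genes fell too (adjusted p = 1.33e-14, and adjusted p = 0.0381 with an estimated correlation), 5 of 18 with 0 up and 13 not passing, and 9 when adjusted over the list alone, among them Cyp3a44 (-2.92 ± 0.18), Fmo2 (-1.29 ± 0.15) and Cux2 (-0.77 ± 0.09). Male-biased genes rose (adjusted p = 1.45e-16, and adjusted p = 0.0563 with an estimated correlation), 4 of 19 with 0 down and 15 not passing, and 10 when adjusted over the list alone. Besides Moxd1 these were Selenbp2 (2.21 ± 0.28), Ugt2b38 (1.64 ± 0.28) and C6 (0.64 ± 0.09), a complement gene. The call of Ugt2b38 held without only 3 of the 12 arrays and reached an adjusted p of 0.117 without KO HFD 3, and that of C6 was lost without KO chow 2 (0.0553), KO chow 3 (0.0676) or KO HFD 3 (0.0548).

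A further 6 lists shifted with HFD in KO mice, each with an adjusted p of 0.127 to 0.646 with an estimated correlation. Of 19 NRF2 targets 3 fell and 5 when adjusted over the list alone (adjusted p = 0.00101), such as Gsta4 (-1.13 ± 0.15). No member of the other 5 lists passed over all genes: fatty acid and triglyceride synthesis was lower (adjusted p = 0.0101), as were oxidative phosphorylation (0.00101), lymphocyte markers (0.00475) and immediate early and heat shock genes (0.0345), and Ahnak binding partners were higher (0.0163). Adjusted over the list alone, 1 lipid synthesis gene, 1 immediate early gene and 1 lymphocyte gene were lower, 2 lymphocyte genes and 3 Ahnak partners were higher, and 0 of 35 oxidative phosphorylation genes passed. Scd1 stood at -1.74 ± 0.34 (adjusted p = 0.0681) and Anxa2, an annexin that binds Ahnak, at 0.72 ± 0.17 (0.164). Oxidative phosphorylation lost its call without KO HFD 1 (adjusted p = 0.0573), lymphocyte markers without KO HFD 3 (0.0705), Ahnak partners without KO chow 3 or KO HFD 3 (up to 0.134), and immediate early genes without KO HFD 1 or KO chow 3 (up to 0.426).

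Other large changes with HFD in KO mice were the rises of Fabp5 (2.63 ± 0.27), Ugt2b37 (2.19 ± 0.26), the esterase gene Ces4a (1.33 ± 0.12), Wif1 (1.12 ± 0.14), an inhibitor of Wnt signalling, Rnase2a (0.99 ± 0.12) and the laminin gene Lamb3 (0.92 ± 0.12). Falls were found for Hamp2 (-3.10 ± 0.33), Cyp3a59 (-2.35 ± 0.25), the transporter gene Slco1a4 (-1.70 ± 0.21) and Akr1d1 (-1.52 ± 0.24), whose call was lost without KO chow 2 (adjusted p = 0.113), KO chow 3, KO HFD 2 or KO HFD 3. A change of at least 2-fold was reached by 28 of the 54 genes, and 1887 genes had an unadjusted p under 0.05. The arrays did not overlap for all 54 changed genes and for 13.8% of all genes, where chance gives 10%. The count was 28 without KO chow 2 and 35 without KO chow 3.

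Whether the effect of the genotype differs between the diets was tested by the interaction, the diet effect in KO minus that in WT, which passed for 783 of 22180 genes, 318 with a positive and 465 with a negative value. With each array centred on its median these were 221 and 623. The count was 1201 with trend and robust settings and 1264 among genes above the median signal. Cyp2b9 had the largest measured value, -11.16 ± 1.32 (adjusted p = 0.000837). Among named genes with negative values Hamp2 (-5.26 ± 0.46), Cyp2b13 (-5.18 ± 0.43), Orm3 (-4.72 ± 0.53) and Rgs16 (-4.55 ± 0.91) came next. Positive values included Moxd1 (4.76 ± 0.41), Hsd3b5 (4.23 ± 0.72), Ugt2b38 (3.98 ± 0.40), Cyp4a12b (3.56 ± 0.25) and Fabp5 (3.52 ± 0.38). Levels near that of Xist enter the values of Cyp2b9, Cyp2b13, Orm3, Moxd1 and Ugt2b38, so their sizes and order are less certain than their directions. Thrsp (-3.94 ± 0.28), Lpin1 (-3.68 ± 0.65), a phosphatase gene of triglyceride synthesis, and Cd36 (-2.34 ± 0.29) also passed, as did Irs2 (2.97 ± 0.43) and Fgf21 (1.96 ± 0.42).

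Of 34 lists 15 passed the interaction test by camera, and 0 did with an estimated correlation. Male-biased genes differed most, with 14 of 19 members positive, 16 adjusted over the list alone (adjusted p = 1.02e-22, and adjusted p = 0.0646 with an estimated correlation). Female-biased genes had 9 of 18 negative, 9 also adjusted over the list alone (1.34e-09, and adjusted p = 0.0851 with an estimated correlation). Drug metabolism genes had 9 of 21 negative, 12 adjusted over the list alone (2.41e-11, and adjusted p = 0.0851 with an estimated correlation). Fibrosis genes had 7 of 28 negative, 9 adjusted over the list alone (2.41e-11, and adjusted p = 0.0902 with an estimated correlation), such as Col3a1 (-1.45 ± 0.20) and Col1a1 (-1.42 ± 0.19). Recruited macrophage markers had 5 of 16 negative, 12 adjusted over the list alone against 1 positive (1.40e-08, and adjusted p = 0.0851 with an estimated correlation). Cell cycle genes had 4 of 27 negative, 9 adjusted over the list alone (1.38e-06, and adjusted p = 0.0884 with an estimated correlation). Fatty acid oxidation genes had 8 of 30 positive, 13 adjusted over the list alone (3.75e-09, and adjusted p = 0.191 with an estimated correlation), such as Ehhadh (1.35 ± 0.13). The other 8 lists had adjusted p values of 0.0884 to 0.569 with an estimated correlation. Of the 15 only NRF2 targets lost their call with 1 array left out, without KO chow 3 (adjusted p = 0.082) or KO HFD 1 (0.0831).

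**Figure D3:**
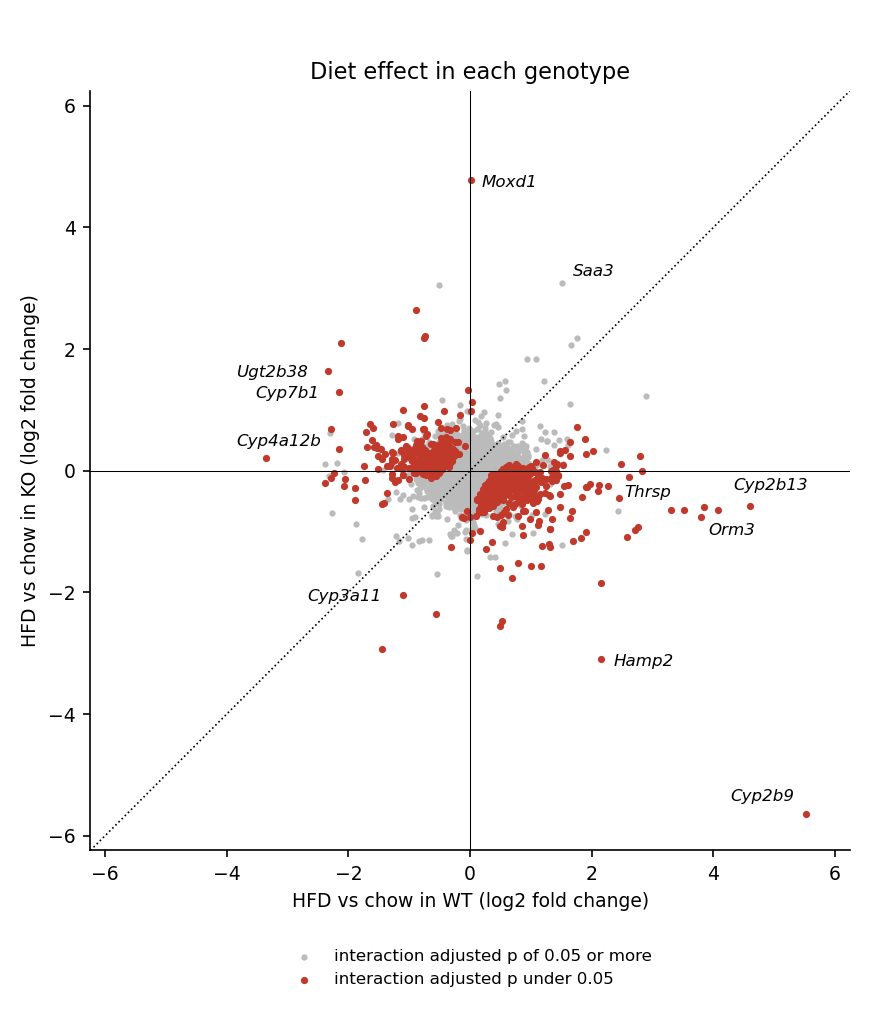
Log2 fold change with HFD in WT (horizontal) and in KO mice (vertical) for 22180 genes; the 783 genes with an interaction adjusted p under 0.05 are red, and the dotted line marks equal effects. Cyp2b9 lies at 5.52 in WT and -5.64 in KO, and Moxd1 at 4.77 in KO only.

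Across genes, which are not independent replicates, the genotype effects on chow and on HFD had a Pearson r = -0.03 and a Spearman rho = 0.02. Of 2333 genes called on either diet 54.2% had the same sign, against 50.7% of all genes, and 0 were called on both. With 2 genes called on chow these values say little on how the 2 effects relate. Male-biased genes averaged -0.52 on chow and 1.42 on HFD, with adjusted p = 0.387 and 0.0544 with an estimated correlation. The diet effects in WT and in KO had r = -0.14 and rho = -0.10, and of 1575 genes called in either genotype 40.9% had the same sign, against 47.1% of all genes, and 22 were called in both. Male-biased Cyp7b1, for example, fell in WT on HFD and stood at 1.30 ± 0.24 (adjusted p = 0.0609) in KO. The differences between KO and WT on HFD ran opposite to the diet effect in WT, with r = -0.80, where unchanged groups that share the 3 WT HFD arrays gave -0.50 in simulation. The covariance was -0.08 against -0.01 in simulation, a difference of -0.06. Both comparisons called 1173 genes: 723 rose with HFD in WT and were lower in KO on HFD, where independent lists would share 59.0, and 447 fell and were higher, where independent lists would share 25.3. Only 3 genes went the same way, and part of the excess may come from the shared arrays, which are too few to be split.

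Averaged over both diets, 1067 genes differed between KO and WT, 321 higher and 746 lower in KO, and 238 and 961 with each array centred on its median. Moxd1 (2.42 ± 0.20), the leptin receptor gene Lepr (1.84 ± 0.47), Cgref1 (1.46 ± 0.32) and Socs2 (1.34 ± 0.16), a suppressor of cytokine signalling, were higher. Cyp2b9 (-2.86 ± 0.66), Cyp2b13 (-2.30 ± 0.22), Hamp2 (-1.96 ± 0.23), Slc22a27 (-1.95 ± 0.20), Lgals1 (-1.93 ± 0.12), Clec2h (-1.89 ± 0.22) and the guanylate-binding protein gene Gbp10 (-1.71 ± 0.12) were lower. Levels near that of Xist enter the values of Moxd1, Cyp2b9, Cyp2b13 and Slc22a27, so their sizes are less certain than their directions. Of 34 lists 14 passed by camera and 0 with an estimated correlation. Cell cycle genes were lower, 10 of 27 and 18 adjusted over the list alone (adjusted p = 2.28e-11, and adjusted p = 0.0766 with an estimated correlation). So were interferon response genes, 7 of 24 and 13 adjusted over the list alone (adjusted p = 4.33e-10, and adjusted p = 0.104 with an estimated correlation). Genes of the unfolded protein response were lower too, with 11 down and 2 up of 23 and 13 and 2 adjusted over the list alone (adjusted p = 1.15e-07, and adjusted p = 0.0959 with an estimated correlation). For genes with an interaction the average stands for neither diet, and Moxd1, Cyp2b9, Cyp2b13, Hamp2 and Slc22a27 are among them. The same holds for the cell cycle, interferon and unfolded protein lists, which passed the interaction by camera (adjusted p = 1.38e-06, 5.50e-06 and 0.0016), though not with an estimated correlation. Their means were -0.09, -0.10 and -0.20 on chow, and -0.48, -0.58 and -0.43 on HFD. Interferon response genes did not pass by camera on chow (adjusted p = 0.0904). On chow the mean of Cyp2b9 was higher in KO than in WT, though without a call.

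Single arrays moved both counts. Interaction calls numbered 444 without WT chow 3, 443 without WT HFD 2, 481 without WT HFD 3, 432 without KO chow 2, 434 without KO chow 3 and 489 without KO HFD 2, and calls averaged over both diets numbered 663 without WT HFD 3 and 645 without KO chow 1. Rgs16 lost its interaction call without KO chow 2 (adjusted p = 0.0507). In the averaged comparison Cyp2b9 lost its call without WT chow 1 or 2, any WT HFD array, or KO HFD 2 or 3 (adjusted p of up to 0.0703). Cgref1 lost its call without WT chow 2, WT HFD 1, KO chow 1 or KO chow 2 (up to 0.0551), and Lepr without any array but WT chow 1 (up to 0.108). An unadjusted p under 0.05 was found for 3845 genes in the interaction and 3982 in the average.

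**Figure D4:**
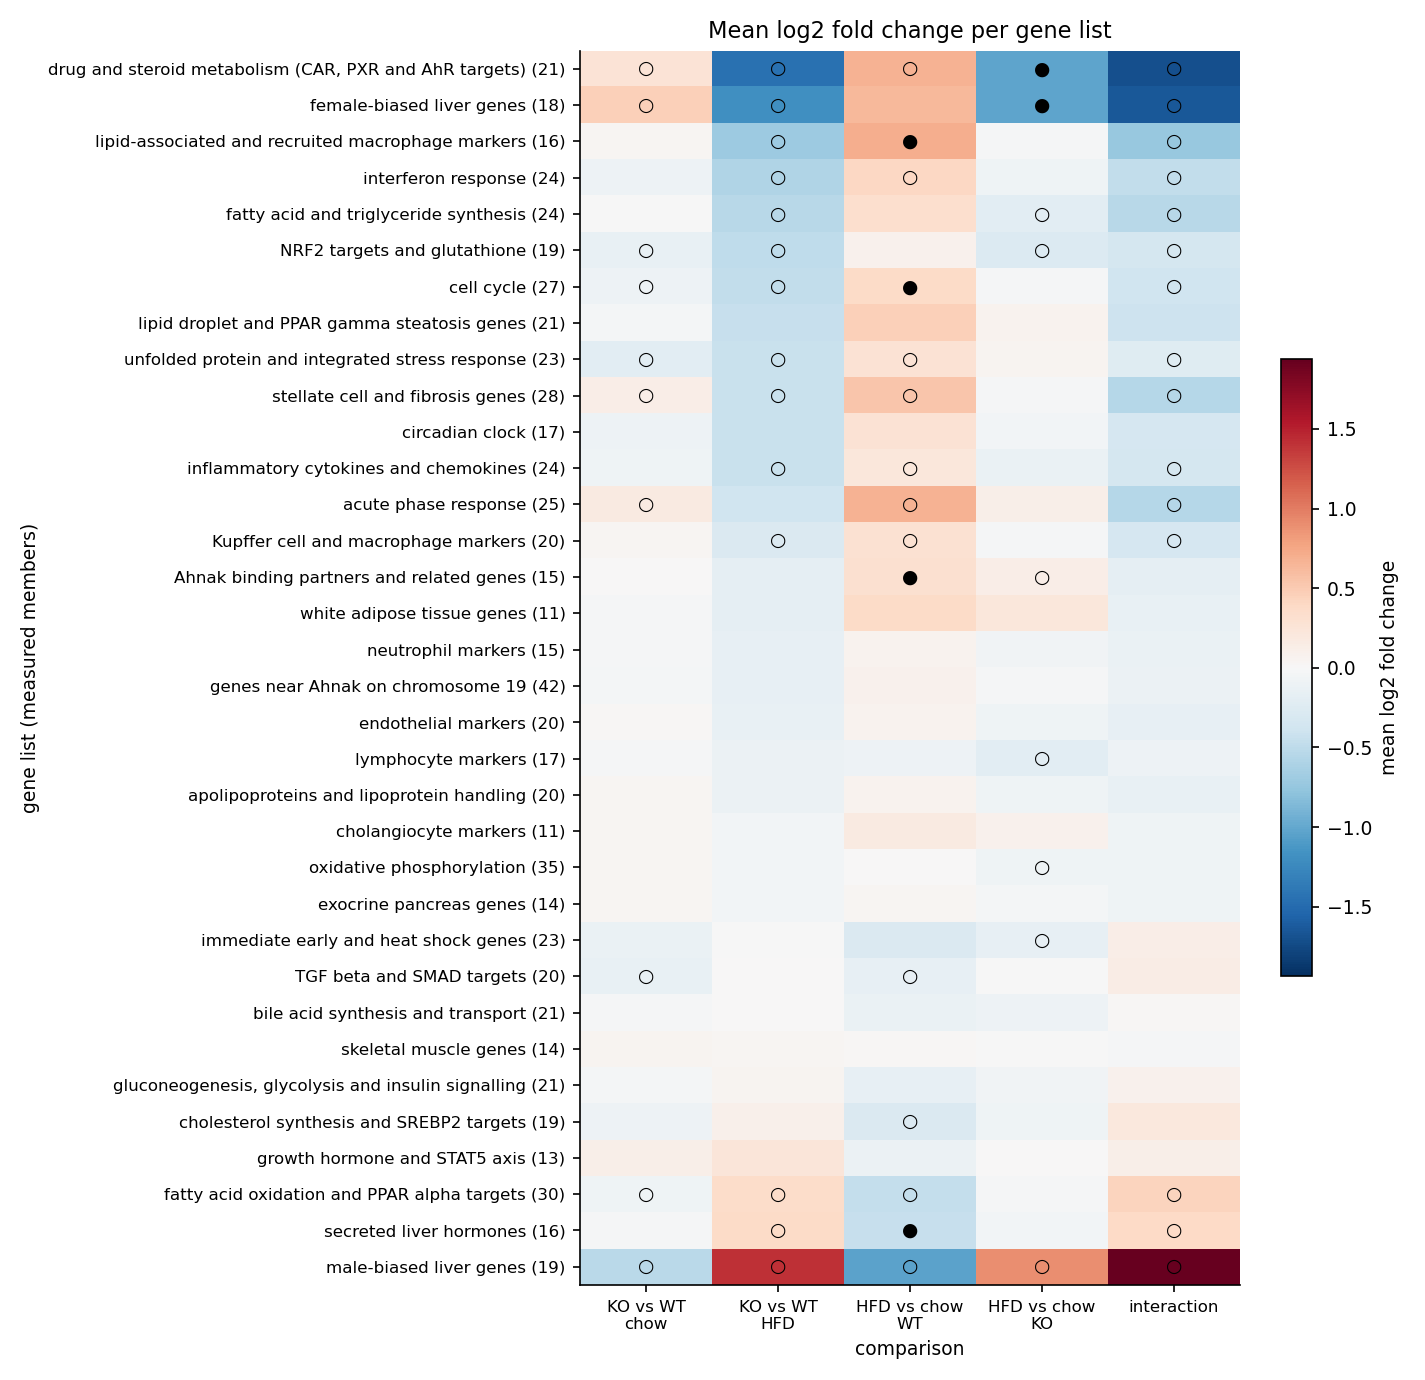
Mean log2 fold change of 34 gene lists (vertical, with the number of measured members) in 4 comparisons of 2 groups and in the interaction (horizontal); open circles mark a camera adjusted p under 0.05, and filled circles mark lists that also pass with an estimated correlation. Filled circles number 4 in WT mice and 2 in KO mice on HFD against chow.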

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

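The tests of adipose tissue, collection time, female animals, cross-hybridisation and growth hormone signalling were chosen after the results were seen. The results here stand out because the effect of the genotype differs between the diets, by the interaction test.

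The interaction passed for 783 genes. Named genes with large values were Moxd1 (4.76), Hsd3b5 (4.23), Ugt2b38 (3.98), Cyp4a12b (3.56), Fabp5 (3.52), Cyp7b1 (3.45), Irs2 (2.97), Ugt2b37 (2.95), Selenbp2 (2.95) and C6 (2.36) above 0, and Cyp2b9 (-11.16), Hamp2 (-5.26), Cyp2b13 (-5.18), Orm3 (-4.72), Rgs16 (-4.55), Slc22a27 (-4.15), Atp6v0d2 (-4.00), Thrsp (-3.94), Ciart (-3.69) and Lpin1 (-3.68) below 0. Levels near that of Xist enter those of Moxd1, Ugt2b38, Cyp2b9, Cyp2b13, Orm3 and Slc22a27, so their sizes are less certain than their directions.

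Lists passing the interaction by camera, none of which passed with an estimated correlation (adjusted p of 0.0646 to 0.569), had a mean log2 value of 1.94 for male-biased and -1.64 for female-biased liver genes, -1.71 for drug and steroid metabolism, -0.34 for NRF2 targets (a call lost without KO chow 3 or KO HFD 1, adjusted p of up to 0.0831), -0.53 for fatty acid and triglyceride synthesis, 0.44 for fatty acid oxidation and 0.39 for secreted liver hormones. The values were -0.24 for the unfolded protein response, -0.56 for the acute phase response, -0.34 for cytokines and chemokines, -0.48 for the interferon response, -0.32 for Kupffer cell markers, -0.73 for recruited macrophage markers, -0.56 for fibrosis genes and -0.39 for cell cycle genes. Medians lay far from the means for female-biased genes (-0.55), drug metabolism (-0.95), NRF2 targets (-0.12), lipid synthesis (-0.09), fatty acid oxidation (0.25), secreted hormones (0.05), the unfolded protein response (-0.48) and the acute phase response (-0.13).

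A signal in data outside the counts of genes came from the 17824 probe sets without a single symbol, of which 131 changed between KO and WT on HFD, 72 higher and 59 lower in KO, and 2 on chow.

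Other splits of the same arrays gave at most 0 changed genes against the real 2 for KO and WT on chow, 0 against 2331 for KO and WT on HFD, 0 against 1543 for the diet in WT and 1 against 54 for the diet in KO. In each of these, 1 of 10 splits, the real one, had as many changed genes, and 10 splits are too few for a share under 0.05. For the average over both diets 1 of 100 splits, the real one, had as many as the real 1067, with 871 the highest of the others, and for the interaction 3 of 100 had as many as the real 783, with 1135 the highest. Splits that kept the HFD groups (6 of those drawn) gave 487 to 871 genes for the average and 365 to 1135 for the interaction, and the other 93 gave at most 1, so that these counts rest on the split of the HFD arrays.

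The livers of WT mice on HFD stand apart from the other 3 groups. Adipose tissue in these samples is argued against as the source of the rise of Cidea. Adipoq, Plin1, Retn and Lep changed with HFD by 0.11 ± 0.12, 0.13 ± 0.12, 0.17 ± 0.14 and -0.16 ± 0.14. The highest upper bound among them was 0.45, below the lower bound of 2.02 for Cidea. The clock genes go with collection at another time of day, or in another feeding state, which was judged by clock genes only. Clock output minus opposite-phase genes was 1.26 higher in WT HFD than in the other 9 arrays, with an SD of 0.44 within groups. Within WT on chow this index ran from -1.44 to 0.03, a wide spread for 1 group. The same index could differ through an effect of diet and genotype on the clock itself, which these arrays do not separate from collection time. Differences in lipid synthesis, fatty acid oxidation, glucose metabolism and hormone genes that rest on the WT HFD arrays are not separated from feeding state either. A response of KO livers to HFD that differs from that of WT livers remains a biological hypothesis. The times of collection and the feeding states would be needed to test it. By camera, male-biased genes were lower on HFD in WT (adjusted p = 7.89e-13) and higher in KO (1.45e-16). Drug metabolism genes were higher in WT (0.0257, a call lost without WT chow 1) and lower in KO (3.11e-18). By camera a response that is only weaker does not describe these lists. With an estimated correlation only the fall of drug metabolism genes in KO passed, so a reversal between the genotypes stays open.

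By camera, male-biased and female-biased liver genes moved in opposite directions in the interaction, though neither list passed with an estimated correlation. With HFD in WT mice only the male-biased list shifted by camera. Female animals among the samples are argued against, since Xist and the 3 measured Y-linked genes each ranged by at most 0.55 over the 12 arrays, where a mix of sexes would part the arrays. Cross-hybridisation within large gene families is argued against for the male-biased members outside these families, of which 6 of 7 had an interaction in the direction of the list. For the male-biased members within these families it stays open, since genes outside them cannot test it. For the female-biased list it cannot be told apart from other causes, since 3 of its 7 members outside these families had one and 4 did not, which keeps it open. Growth hormone signalling in the liver cannot be told apart from other causes: 1 of Socs2, Cish, Igf1 and Igfals had an interaction in the direction of the male-biased list (Socs2, 1.82 ± 0.31), and Cish (0.05), Igf1 (0.29) and Igfals (-0.0012) did not, which keeps the question open.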

How the results depend on the processing

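No named gene or list with a call reversed under the alternatives it was run with, lists not being run with all of them, and where a count moved the cause was not tested unless the alternative uses fewer genes or arrays. For KO against WT on chow the 2 genes became 18 with trend and robust settings (5 higher, 13 lower), 15 among genes above the median signal (4 and 11), so that the balance turned from 2 higher and 0 lower, 0 with only the arrays compared, 1 at 2-fold and 0 to 5 with 1 array left out. Counts at 2-fold were 295 for KO against WT on HFD, 55 for the average, 206 for the diet in WT, 28 for the diet in KO and 275 for the interaction. Without the 2-fold limit and with 1 array left out the counts ran from 1506 to 2326, 645 to 1045, 815 to 1691, 28 to 79 and 432 to 718. The diet in KO gave 124 with trend and robust settings, 111 above the median signal and 21 with only the arrays compared, and the interaction gave 1201 and 1264 with the first 2 of these. Lists passing with an estimated correlation numbered 0 on chow, 0 on HFD, 0 for the average, 4 for the diet in WT, 2 for the diet in KO and 0 for the interaction, and with fry 0, 15, 10, 14, 5 and 14 in the same order. Lists passing on chow numbered 6 to 11 with 1 array left out. Ahnak on HFD was -0.49 (adjusted p = 0.0506) after quantile normalization and -0.62 to -0.37 with 1 array left out, losing its call in 9 of 12. Dim genes limit the tests, and 13513 genes lay above the median signal.

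The groups share only replicate numbers. With the replicate block the counts were 0 on chow, 2073 on HFD, 804 for the average, 1290 for the diet in WT, 40 for the diet in KO and 612 for the interaction. Arrays with the same number correlated at -0.06 to 0.08 after removal of group means, 0 of 18 pairs over 0.1, and 1 of 12 arrays was closest to its own number.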

Other observations

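Circadian clock genes did not shift as a list between KO and WT on HFD (adjusted p = 0.107), with 2 up and 5 down of 17, 3 and 5 adjusted over the list alone. Ciart fell by 2.89 ± 0.32 and Dbp by 1.19 ± 0.26, while Arntl, the core activator, rose by 1.08 ± 0.29. Averaged over both diets the list was lower (adjusted p = 0.0145, and adjusted p = 0.581 with an estimated correlation), a call lost without WT chow 3 (0.105) or KO HFD 3. Of 13 genes of the growth hormone and STAT5 axis 3 rose and 1 fell on HFD, 3 and 2 adjusted over the list alone (adjusted p = 0.671; mean 0.23, median -0.15), with Egfr up by 1.45 ± 0.12 and Socs2 by 2.25 ± 0.22. Ahnak binding partners did not shift by camera between KO and WT on HFD (adjusted p = 0.23) but passed with fry (adjusted p = 0.00765). Their mean was -0.18 and their median 0.02. Anxa2 fell by 1.31 ± 0.17, Myof by 0.50 ± 0.10 and Anxa1 by 0.56 ± 0.13, the same 3 of 15 as adjusted over the list alone. The call of Anxa1 was lost without KO HFD 1 (adjusted p = 0.0537), KO HFD 2 (0.0668), WT HFD 2 (0.0513) or WT HFD 3 (0.0518). In WT mice they were higher on HFD (adjusted p = 0.000672, and adjusted p = 0.048 with an estimated correlation), 3 of 15 and 7 adjusted over the list alone, with Anxa2 up by 1.76 ± 0.17. Of 42 genes near Ahnak on chromosome 19 only Slc22a27, B3gat3 (0.46 ± 0.09), Fads2 (0.34 ± 0.07) and Slc22a26 (-1.17 ± 0.32) changed on HFD, 2 up and 2 down, as also adjusted over the list alone (adjusted p = 0.518). Fads2 lost its call without WT HFD 1 (0.0507), and Slc22a26 without KO HFD 2, KO HFD 3 or any WT HFD array (up to 0.112).

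Other lists did not shift between KO and WT on HFD. Adjusted p values were 0.519 for cholesterol synthesis, where 2 of 19 rose, among them Hsd17b7 by 1.27 ± 0.09, and 0.903 for apolipoproteins (3 up and 3 down of 20). They were 0.671 for TGF beta targets (3 up and 1 down of 20, with Id2 up by 0.99 ± 0.17) and 0.33 for oxidative phosphorylation (1 down of 35, Sdha, by 0.33 ± 0.08), and 0.875 for immediate early and heat shock genes (1 up of 23, Egr1, by 1.43 ± 0.24). Markers of other cells gave 0.251 for neutrophils (0 of 15), 0.251 for lymphocytes (1 up of 17, Cd4, by 0.80 ± 0.18), 0.23 for endothelium (3 down of 20, such as Lyve1, -1.35 ± 0.37) and 0.622 for cholangiocytes (0 of 11). Genes of other tissues gave 0.901 for white fat (1 down of 11, Cidea), 0.978 for exocrine pancreas (0 of 14) and 0.602 for skeletal muscle (0 of 14). Adjusted over the list alone these counts were the same, except for 0 in oxidative phosphorylation and 1 up and 1 down among lymphocyte markers. Cd4 lost its call without WT HFD 3 (0.0511), Sdha without KO HFD 1, KO HFD 3 or any WT HFD array (up to 0.0775), and Lyve1 without any 1 of the 6 HFD arrays (up to 0.109). In WT mice TGF beta targets were lower on HFD (adjusted p = 0.0272, and adjusted p = 0.451 with an estimated correlation), 3 down and 1 up of 20, 5 and 1 adjusted over the list alone. This call was lost without WT chow 1 (0.144), WT chow 3 or WT HFD 2.

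Nnt, a mitochondrial gene of which some C57BL/6 substrains carry a deletion, differed between arrays of the same group. Its signals were 9.81, 10.75 and 10.78 in WT on chow, 10.76, 10.75 and 10.75 in WT on HFD, 9.69, 10.48 and 10.46 in KO on chow, and 10.19, 9.39 and 10.30 in KO on HFD. Its SD within groups was 0.435, where the median of 2169 genes of similar signal was 0.104 and 1.66% had a larger SD. No explanation of this spread was tested.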
